A study of Mus musculus with 4 samples.

How the data were processed

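RNA-seq libraries of the mouse microglial cell line BV-2, an immortalised line used as a model of brain macrophages, were compared after lipopolysaccharide (LPS), a bacterial cell wall component sensed by Toll-like receptor 4. The labels give 4 samples, 2 controls and 2 treated with LPS at 10 ng/ml for 4 h. Groups and replicate numbers were taken from the sample titles. The labels do not say that replicates of a group came from separate cultures, so p-values of single genes measure only the spread between these samples, which may be technical. The growth text in the labels also describes the shaking of mixed glial cultures, whereas every sample is labelled as the cell line.

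Per the labels' protocols, ribosomal RNA was removed from total RNA, and directional libraries made with random primers were sequenced as paired ends on a HiSeq 2000. The deposited table holds whole-number read counts per RefSeq transcript record. It is named as normalised, but its columns sum to different totals, every whole number from 1 to 59 occurs in each column, and median-of-ratios factors run from 0.745 to 1.18 rather than lying at 1, so the deposited counts were treated as raw. CASAVA 1.8.2, Trimmomatic 0.33, TopHat2 2.0.10, Cufflinks 2.2.1, HTSeq 0.6.1 and the genome build mm10 are named, per the submitters' processing notes. The role of each tool, its settings, the annotation release and the strand setting of the counting are not given in the sources used here.

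The table has 32915 records, of which 28566 are coding and 4349 non-coding. RefSeq gene tables of the GRCm38.p6 assembly, the assembly behind mm10, gave a symbol to 32483 records, covering 23779 genes, and no symbol to 432. Records without a symbol other than NR_046233 took at most 0.136% of a library's counts. Gene positions are 1-based on that assembly. A gene had 1 record in 19014 cases and 2 or more in 4765, and records were analysed separately because the table counts them separately.

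Library totals ran from 2778686 to 3368693 counts. NR_046233 held 30.6% to 38.2% of them and Lars2 18.8% to 26.6%. With Rmrp, Rpph1 and Mir6236, these 5 records took 53.4% to 67.5%, which left 902176 to 1425303 counts per library for all others. The libraries carry no molecular identifiers, so intervals and floors given here cover counting error only.

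Records were kept by edgeR's filterByExpr with a minimum count of 10, which left 6981 records of 6910 genes. Library sizes were scaled by TMM, and normalised counts are counts divided by the effective library size and multiplied by the mean effective size of 3108147. LPS was compared with control by edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on all 4 libraries without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design written in advance set a log-scale limma test for normalised values and this count test for raw counts, and the latter applied. Values are given as mean ± SD of normalised counts with n = 2 per group, and changes as fitted log2 fold changes with the standard error. The common biological coefficient of variation was 15.8%. For genes with 0 counts in both control libraries, the fold is a lower bound against a floor of 3 counts over the group. For 1 to 3 control counts, the rate ratio is given with its exact 95% interval.

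The comparison, its test, the naming rule, a set of other settings and 33 gene lists were written before the data were examined. Of the lists, 32 had a record in the table, and the 25 with at least 5 measured members were tested by camera (limma 3.58.1) with a preset correlation of 0.01. With that preset, camera sets list members against the spread across genes, so its p-values do not measure the spread between samples. The correlation estimated from the data was far higher for some lists, such as 0.611 for cytokines and 0.691 for histone genes. For others it was near or below the preset. With an estimated correlation, camera takes its degrees of freedom from the 4 libraries rather than from the number of genes. It can then hardly call a list, so a lost call does not decide whether that list changed. A list member with several tested records was represented by the most abundant. Measured members were 8 of 22 cytokine, 9 of 24 chemokine, 14 of 20 effector, 18 of 24 NF-kB and 21 of 40 interferon-stimulated genes. A gene near 0 in the controls could pass the count filter only through LPS, so shares of measured members that rose lean upward. The list of mitochondrially encoded genes had no record to analyse, so it is not analysed here. The histone list was a symbol pattern that also takes linker histone genes and H13, which is not a histone gene, and the pattern for ribosomal protein genes also takes Rps19bp1 and S6 kinase genes, 7 of them measured. Counts of calls are given over all genes tested and adjusted over the list alone. The values of some list members are not reported here.

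The genes named were set by a rule fixed in advance. It takes 19 sentinel genes of microglia and LPS responses, the 5 largest rises and 5 largest falls among genes with a mean of at least 100 normalised counts in the higher group and groups that do not overlap, up to 3 called members per list by size of change, again with groups that do not overlap (or the most abundant member of a list with no call), and the 5 called genes with the largest difference of means. Small RNAs and unnamed gene models were left out of the rankings. The rule named 70 tested genes.

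The fit was tested on simulated counts for the 6981 records, with the means and library sizes of this comparison and its dispersion as a trend on the mean. It recovered 51 of 100 records changed 2-fold, or 84.1% of those with a mean count of at least 100, and 98 of 100 changed 4-fold. Of 154 calls, 5 were false, and 0 of 100 lists of unchanged records were called. Records were drawn independently, with the same dispersion in both groups. Correlation between genes and the larger spread of the control libraries were thus left out. These error rates, above all that of the lists, may therefore not hold for the data.

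Alternatives set in advance were no filter on low counts, a mean of at least 50 normalised counts, DESeq2 size factors in edgeR, the Wald test of DESeq2 1.42.0, a replicate block, each library left out in turn, and for lists an estimated correlation and fry. With a library left out, the lone library of its group is assumed to vary like the other group. Adjusted p from such fits leave out the spread within that group. Added after the data were seen were a robust dispersion, the fit without the 5 most abundant records, counts summed per gene, limma-voom, the pattern lists without S6 kinase genes, Rps19bp1, H13 and H1f0, and a trend on GC content and transcript length fitted in each library and entered as an offset. GC content and length came from the GENCODE M21 transcript matched to each record, found for 6924 of the records tested (99.2%). The trend fit was also tested on simulated counts with a GC slope added to 1 library, where it recovered 148 of 200 changed records, against 102 before the trend was removed, and 6.33% of its calls were false. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the other steps.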

Results

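Gene expression was measured by RNA-seq in mouse BV-2 microglial cells kept as controls or treated with LPS at 10 ng/ml for 4 h, with 2 libraries per group. The totals were 2778686 and 3059196 counts in the control libraries and 3368693 and 3082538 in the LPS libraries. Without the 5 most abundant records, 902176 and 1425303 counts remained in the controls and 1423391 and 1327707 after LPS. Normalised counts of the control libraries had a Pearson correlation of 0.947 across genes on the log2 scale and those of the LPS libraries 0.979, where genes are not independent replicates. In both pairs the libraries differed by more than counting error, with chi-square per degree of freedom of 7.21 and 1.87. The comparison asks which transcripts of a microglial line respond to LPS.

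LPS raised transcripts of inflammatory mediators by the largest margins. Csf3, the granulocyte colony-stimulating factor gene (NM_009971, chromosome 11, 98700183 to 98703631), had 0 counts in both control libraries and 730 ± 4.79 normalised counts after LPS (SD, n = 2), at least 461-fold higher with an adjusted p of 1.6e-07. Cxcl2, a neutrophil chemokine (NM_009140, chromosome 5, 90903899 to 90905938), had 1 count over both controls and 1452 ± 69.7 normalised counts after LPS, a rate ratio of 2750 with a 95% interval of 493 to 108646. Il1b, which encodes interleukin-1 beta (NM_008361, chromosome 2, 129364569 to 129371164), rose from 3.94 ± 1.59 to 2030 ± 57.8 normalised counts, a log2 fold change of 8.88 (SE 0.303, adjusted p 1.79e-08). The deepest falls were in Gpr183, an oxysterol receptor gene (NM_183031, chromosome 14, 121952331 to 121965193), from 156 ± 6.56 to 8.92 ± 5.69 normalised counts (log2 fold change -4.09, SE 0.354, adjusted p 2.52e-05), and Rab7b, a gene of endosomal trafficking (NM_145509, chromosome 1, 131688681 to 131715443), from 165 ± 11.9 to 24.7 ± 0.363 (log2 fold change -2.73, SE 0.251, adjusted p 3.75e-05). Over the alternatives the log2 fold change of Gpr183 ran from -4.94 to -3.57.

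Of 6981 records tested, 267 were higher and 119 lower after LPS at an adjusted p below 0.05 in edgeR's quasi-likelihood test, and these 386 records belonged to 386 genes. At least 2-fold changes made up 236 of the rises and 107 of the falls. The 5 largest differences of mean level were those of Acod1, whose enzyme makes itaconate, Odc1, Saa3, Ptgs2 and Ccl3. Odc1, the ornithine decarboxylase of polyamine synthesis, rose from 2202 ± 238 to 5532 ± 233 normalised counts (log2 fold change 1.33, adjusted p 0.000994). The counts changed with the library left out. Without an LPS library the spread came from the control pair alone, and without a control library from the LPS pair alone. The control pair differed more, with chi-square per degree of freedom of 7.21 against 1.87 in the LPS pair. These counts therefore do not show that calls hang on 1 library. With a trend on GC content and transcript length removed, 435 were higher and 337 lower, so that 56.3% rather than 69.2% of calls were higher, and the 386 genes were all among them, while on simulated counts 6.33% of the calls of that fit were false. Histone genes, a list fixed in advance as a sign of RNA quality, were lower after LPS with a median log2 fold change of -0.47 (camera adjusted p 6.51e-09, and 0.534 with an estimated correlation). The log2 ratio of the control libraries went with the GC content of the transcript (Spearman's rho 0.761 across 4091 records) more than that of the LPS libraries (0.340), where genes are not independent replicates.

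**Figure D1:**
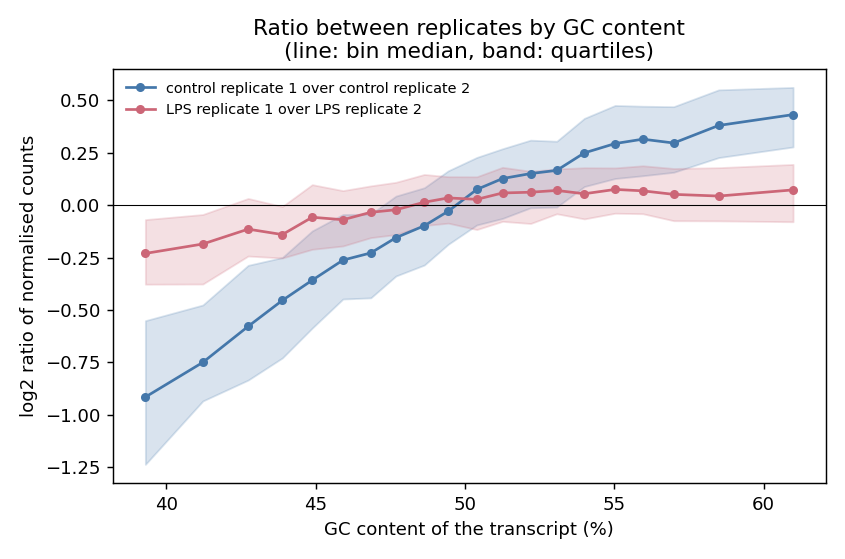
Median log2 ratio of replicate 1 over replicate 2 (line) with its quartiles (band) in 20 bins of transcript GC content in percent, for the control libraries and the LPS libraries. The control ratio had a median of -0.59 below the lower GC quartile and 0.35 above the upper one, and the LPS ratio -0.14 and 0.06.

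**Figure D2:**
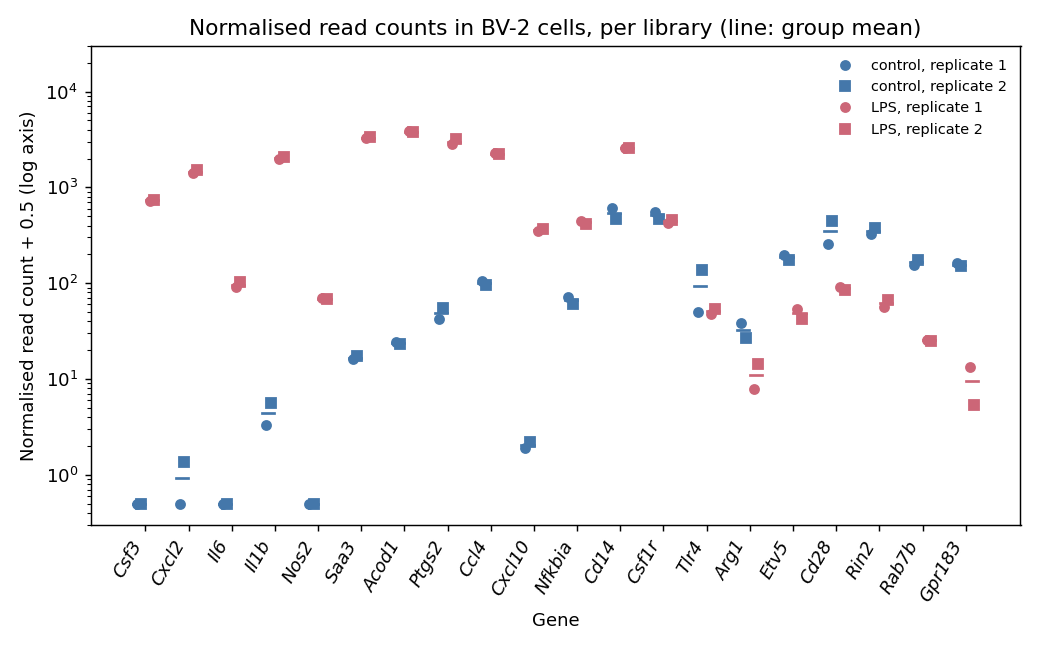
Normalised read counts plus 0.5 on a log axis for 20 genes in each of the 4 libraries, with circles for replicate 1, squares for replicate 2, blue for control, red for LPS and a short line at each group mean. Il1b reached 1990 and 2071 in the LPS libraries against 2.81 and 5.06 in the controls, and Gpr183 lay below its controls in both LPS libraries.

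Among 8 measured cytokine genes, 5 rose (Csf3, Il1a, Il1b, Il6 and Osm) and 3 did not pass the test. Il6 (NM_031168, chromosome 5, 30013114 to 30019975) had 0 control counts and 96.2 ± 9.2 normalised counts after LPS, at least 60.7-fold higher. Il1a had 3 control counts in all and a rate ratio of 360 with an interval of 123 to 1749. The median log2 fold change of the cytokine list was 5.76, or 4.53 with genes absent from the controls at their bound, and 7 members passed when adjusted over the list alone. Over the alternatives this median ran from 3.33 to 8.35. Camera called the list higher with an adjusted p of 5.17e-48, and the adjusted p was 0.109 with an estimated correlation.

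Chemokine genes rose in 7 of 9 measured cases, and 8 rose when adjusted over the list alone. Ccl4, which encodes an inflammatory chemokine (NM_013652, chromosome 11, 83648624 to 83664683), rose from 100 ± 7.75 to 2247 ± 47.9 normalised counts (log2 fold change 4.49, SE 0.206). Its neighbour Ccl3, whose annotated span overlaps it, rose by 3.19, and the counting of reads in the span they share is not described in the sources used here. Ccl2, the monocyte chemoattractant, rose from 247 ± 45.4 to 2018 ± 391 (log2 fold change 3.02). Cxcl10, an interferon-inducible chemokine, had 3 control counts and a rate ratio of 224 with an interval of 76.5 to 1090. Chemokine genes as a list had a median of 3.19 and a camera adjusted p of 4.1e-61, and the adjusted p was 0.0929 with an estimated correlation.

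Inflammatory effector and acute-phase genes rose in 13 of 14 measured cases, and in 14 when adjusted over the list alone. Some of them, such as Nos2 and Lcn2, passed the count filter only through the LPS libraries. Saa3, an acute-phase apolipoprotein (NM_011315, chromosome 7, 46711998 to 46719615), rose from 16.2 ± 0.995 to 3311 ± 71.0 normalised counts (log2 fold change 7.65). Acod1 (NM_008392, chromosome 14, 103047012 to 103056573) rose from 23.3 ± 0.795 to 3812 ± 35.5 (log2 fold change 7.35), and Ptgs2, the inducible cyclooxygenase (NM_011198, chromosome 1, 150100031 to 150108234), from 48.1 ± 8.36 to 3008 ± 265 (log2 fold change 5.94). Nos2, the inducible nitric oxide synthase (NM_010927, chromosome 11, 78920787 to 78960226), had 0 control counts and 68.4 ± 1.32 normalised counts after LPS, at least 43.2-fold higher. Lcn2, a siderophore-binding lipocalin, had 1 control count and a rate ratio of 478 with an interval of 85.5 to 18932. As a list these effector genes had a median of 3.77 and a camera adjusted p of 3.36e-74, and the adjusted p was 0.109 with an estimated correlation. The effector list median ran from 3.29 to 5.91 over the alternatives.

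Genes of the NF-kB system and of its feedback rose in 14 of 18 measured cases, and in 16 when adjusted over the list alone. Nfkbia, which encodes the inhibitor IkB-alpha (NM_010907, chromosome 12, 55489409 to 55492647), rose from 66.3 ± 7.76 to 433 ± 22.5 normalised counts (log2 fold change 2.72, SE 0.212). Tnfaip2 rose by 3.62 on the log2 scale, and Traf1, a TNF receptor adaptor, had 2 control counts and a rate ratio of 362 with an interval of 99.9 to 2996. Bcl3, an atypical IkB protein, had 3 control counts and a rate ratio of 10.2 with an interval of 3.21 to 52.0, and its adjusted p was 0.149 without LPS replicate 2 and 0.107 in the DESeq2 Wald test, and ran from 4.11e-05 to 0.149 over the alternatives. For the NF-kB list the median was 1.99 with a camera adjusted p of 4.73e-39, and the adjusted p was 0.0929 with an estimated correlation.

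Interferon-stimulated genes rose in 13 of 21 measured cases, and in 18 when adjusted over the list alone. Rsad2, which encodes the antiviral protein viperin (NM_021384, chromosome 12, 26442743 to 26456452), rose from 5.49 ± 1.79 to 154 ± 22.9 normalised counts (log2 fold change 4.71, SE 0.347). Rtp4 had 2 control counts and a rate ratio of 45.9 with an interval of 12.4 to 385, and Gbp2, one of a family of similar guanylate-binding proteins that may share reads, was at least 9.91-fold higher from 0 control counts. The list median was 2.35 with a camera adjusted p of 5.52e-30, and the adjusted p was 0.115 with an estimated correlation.

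Immediate early genes and MAPK phosphatase genes rose in 12 of 16 measured cases and fell in 1, Dusp6, a phosphatase of ERK, with a log2 fold change of -1.37. Socs3, a suppressor of cytokine signalling, rose from 7.17 ± 1.79 to 126 ± 2.33 normalised counts (log2 fold change 4.17). Dusp8 rose by 3.02 and Dusp1 by 2.58 on the log2 scale, with an adjusted p of 0.138 for Dusp8 without LPS replicate 1 and 0.136 for Dusp1 without LPS replicate 2, each the highest over the alternatives, where the lowest were 3.07e-05 and 1.53e-07, and the DESeq2 Wald test gave Dusp8 0.100. The log2 fold change of Dusp1 ran from 1.72 to 3.65 over the alternatives. Adjusted over the list alone, 14 rose and 1 fell. The list median was 1.85 with a camera adjusted p of 1.32e-19, and the adjusted p was 0.169 with an estimated correlation.

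Of 12 measured Toll-like receptor and adaptor genes, 4 rose (Cd14, Tlr2, Irak3 and Ticam1) and 1 fell (Tlr13, log2 fold change -0.94). Cd14, the LPS co-receptor (NM_009841, chromosome 18, 36725064 to 36726815), rose from 537 ± 93.7 to 2571 ± 23.5 normalised counts (log2 fold change 2.26). Tlr2 rose from 274 ± 72.6 to 1267 ± 91.5, and Irak3, an inhibitor of receptor signalling, rose by 3.20 on the log2 scale. Tlr4, the LPS receptor itself, had 93.8 ± 63.1 normalised counts in controls and 50.5 ± 4.69 after LPS, which did not pass the test (log2 fold change -0.94, SE 0.392, adjusted p 0.269). Tlr4 had 49.2 normalised counts in control replicate 1 and 138 in control replicate 2, against 47.2 and 53.8 after LPS. The fall thus rests on control replicate 2. Without control replicate 1 the log2 fold change of Tlr4 was -1.45. Without a filter on low counts it was -0.91 with an adjusted p of 0.0268. With the GC and length trend removed it was -1.06 with an adjusted p of 0.00634. Over the alternatives it ran from -1.45 to 0.03, with an adjusted p of up to 0.965. Adjusted over the list alone, 5 rose, with Myd88 as the added gene, and 1 fell. The median of these 12 genes was 0.01 and their mean 0.60, with a camera adjusted p of 0.00144, and the adjusted p was 0.19 with an estimated correlation and 0.0632 among records with a mean of at least 50 normalised counts, where the median was -0.10. Without LPS replicate 2 the median was -0.14, with the direction of the test still higher.

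Among 14 measured inflammasome and cell death genes, 6 rose and none fell, with 8 higher when adjusted over the list alone. Nlrp3, an inflammasome sensor (NM_145827, chromosome 11, 59541569 to 59566955), rose from 59.5 ± 0.599 to 552 ± 40.0 normalised counts (log2 fold change 3.21). Tnfrsf1b, which encodes TNF receptor 2, rose by 3.04, and Bcl2a1b, an anti-apoptotic gene with near-identical copies that can share reads, by 2.85. The list median was 1.23 with a camera adjusted p of 2.47e-11, and the adjusted p was 0.109 with an estimated correlation.

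**Figure D3:**
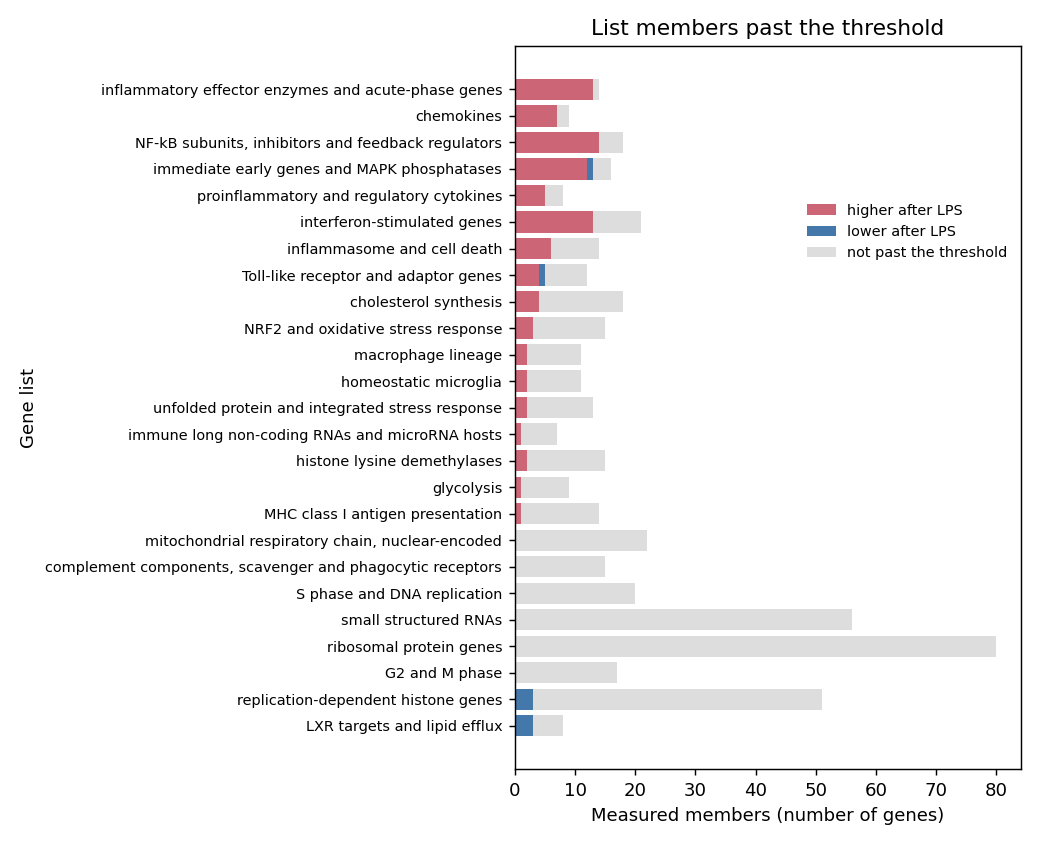
Number of measured members of each of the 25 tested gene lists that were higher (red), lower (blue) or not past the threshold (grey) after LPS. Inflammatory effector genes had 13 of 14 members higher, and the symbol pattern for ribosomal protein genes had 80 members, 8 of them genes of another kind, with none past the threshold.

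Lipid and stress genes moved in smaller numbers. Cholesterol synthesis genes rose in 4 of 18 measured cases (Hsd17b7, Insig1, Msmo1 and Fdft1), and in 7 when adjusted over the list alone. Insig1, a feedback regulator of sterol synthesis, rose from 384 ± 65.1 to 863 ± 71.2 normalised counts (log2 fold change 1.16), Hsd17b7 rose by 1.23 and Msmo1 by 1.03. The cholesterol list median was 0.57 with a camera adjusted p of 7.29e-05, and the adjusted p was 0.19 with an estimated correlation. LXR targets and lipid efflux genes fell in 3 of 8 measured cases. Scd2, a fatty acid desaturase, went from 990 ± 75.6 to 466 ± 12.4 normalised counts (log2 fold change -1.08), and Abcg1, a cholesterol exporter, and Mylip had log2 fold changes of -1.69 and -1.52. Adjusted over the list alone, the same 3 genes fell. The LXR list median was -0.23 with a camera adjusted p of 0.00555, and the adjusted p was 0.45 with an estimated correlation. The LXR list was not called without control replicate 1 (adjusted p 0.0628) or without LPS replicate 2 (0.0678), nor with a mean of at least 50 normalised counts (0.121) or by fry (0.0961), and the DESeq2 Wald test called 1 of its 8 genes, with an adjusted p of 0.0692 for Mylip and 0.0586 for Abcg1. Without LPS replicate 2 the adjusted p was 0.132 for Hsd17b7, 0.140 for Msmo1, 0.244 for Scd2, 0.145 for Mylip and 0.129 for Abcg1, and without LPS replicate 1 it was 0.0895 for Insig1, 0.123 for Msmo1, 0.156 for Scd2 and 0.0769 for Mylip.

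NRF2 and oxidative stress genes rose in 3 of 15 measured cases, also when adjusted over the list alone. Slc7a11, the cystine transporter, rose from 22.4 ± 13.7 to 344 ± 43.9 normalised counts (log2 fold change 3.84), Nfe2l2, which encodes NRF2 itself, by 1.26 and Srxn1, a sulfiredoxin, by 0.97. Over the alternatives the log2 fold change of Slc7a11 ran from 3.43 to 4.75. The NRF2 list had a median of 0.09 and a camera adjusted p of 0.0167, the adjusted p was 0.268 with an estimated correlation, and it was 0.0865 without control replicate 2. Of 13 unfolded protein and integrated stress response genes, Herpud1 rose by 2.00 and Ppp1r15a by 1.72 on the log2 scale, the same 2 when adjusted over the list alone. The median of that list was -0.17 and its mean 0.13, and camera did not call it (direction higher, adjusted p 0.581), whereas fry, which does not compare a list with other genes, called it higher (adjusted p 0.0129). Slc2a1, the glucose transporter GLUT1, rose from 150 ± 25.3 to 319 ± 9.31 normalised counts. It was the 1 gene past the threshold among the 9 measured of 20 glycolysis genes, also when adjusted over the list alone (camera adjusted p 0.567). Gapdh, which has 2 records, was among those below the count filter, so most of this list was not measured. None of 22 nuclear-encoded respiratory chain genes passed in edgeR, DESeq2 or limma-voom or when adjusted over the list alone, and 0 had an unadjusted p below 0.05 (camera adjusted p 0.863). The most abundant of them, Atp5b, had 2820 ± 261 and 2848 ± 77.1 normalised counts. Without LPS replicate 1, the adjusted p was 0.301 for Srxn1 and 0.0805 for Slc2a1, and without LPS replicate 2 it was 0.278 for Srxn1 and 0.136 for Slc2a1.

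Markers of microglial identity gave few calls. Of 11 measured genes of homeostatic microglia, Gpr84, a receptor for medium-chain fatty acids, rose from 18.8 ± 11.1 to 143 ± 24.6 normalised counts (log2 fold change 3.02), and Rhob, a small GTPase, rose by 1.06. Over the alternatives the log2 fold change of Gpr84 ran from 2.41 to 3.70. Gpr84 is known as a gene that inflammatory stimuli induce. The other 9 genes had negative values that did not pass over all genes, and 4 of them passed when adjusted over the list alone, among them the nucleotide receptor genes P2ry13 and P2ry6 with log2 fold changes of -1.04 and -0.73. The median of this list was -0.73 and camera did not call it (adjusted p 0.453). Csf1r, the receptor for colony-stimulating factor 1, had 512 ± 55.7 normalised counts in controls and 441 ± 17.5 after LPS (log2 fold change -0.21, adjusted p 0.728). For Rhob the adjusted p was 0.276 without LPS replicate 1, 0.133 without LPS replicate 2 and 0.0747 with a mean of at least 50 normalised counts.

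None of 15 complement, scavenger and phagocytic receptor genes passed over all genes in edgeR, DESeq2 or limma-voom, 4 had an unadjusted p below 0.05, and 2 were lower when adjusted over the list alone (Fcgr1 and Fcgr3, log2 fold changes -0.66 and -0.68). C1qb had 1119 ± 351 and 892 ± 58.7 normalised counts (adjusted p 0.6). Camera gave the complement list, with a median of -0.32, an adjusted p of 0.152. Without control replicate 2 the list median was -0.30 and the log2 fold change of C1qb -0.62. Of 4 alternative activation genes, Tgm2, a transglutaminase, rose, with 2 control counts and a rate ratio of 21.2 with an interval of 5.54 to 180.0. Arg1, the arginase of alternatively activated macrophages, had 32.1 ± 8.35 and 10.5 ± 4.45 normalised counts (log2 fold change -1.57, adjusted p 0.0558), and it was lower with Mrc1 when adjusted over the list alone, where Tgm2 was also higher. These 4 genes had a median of -0.21 and a mean of 0.56, which differ in sign, and were too few for camera. The adjusted p of Arg1 was 0.0335 without control replicate 1, 0.00163 without control replicate 2, 0.00326 without a filter on low counts and 0.0124 with the GC and length trend removed, and over the alternatives it reached 0.548.

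In the MHC class I list, 1 of 14 measured genes rose, H2-Q4 by 1.32 on the log2 scale, and its reads can be shared with related class I genes. H2-K1 passed with it when adjusted over the list alone, the list had a camera adjusted p of 0.126, and the adjusted p of H2-Q4 was 0.157 without LPS replicate 1 and 0.0599 without LPS replicate 2. The DESeq2 Wald test gave H2-Q4 an adjusted p of 0.0837 and called 0 of the 14 genes, of which 4 had an unadjusted p below 0.05 in edgeR, and limma-voom called 1. None of 3 measured MHC class II and costimulation genes passed in edgeR, DESeq2 or limma-voom, 1 had an unadjusted p below 0.05, and their median of -0.14 and mean of 0.34 differ in sign. Among them was Cd86 with 119 ± 23.5 and 103 ± 8.81 normalised counts, and Cd274 was higher when adjusted over the list alone. Of 11 macrophage lineage markers, Cd14 and Spi1 rose, Spi1, which encodes the myeloid factor PU.1, by 1.15, and Laptm5 and Fcgr3 were lower when adjusted over the list alone. The macrophage list had a median of -0.18 but a mean of 0.12, with camera's direction higher at an adjusted p of 0.542, and the adjusted p of Spi1 was 0.0514 without LPS replicate 1 and 0.0823 without LPS replicate 2. None of the 10 genes listed for astrocytes, of the 10 for neurons, of the 10 for oligodendrocytes or of the 9 with a record for lymphocytes and neutrophils reached the count filter. Flt1, the 1 measured gene of the fibroblast and endothelial list, had 62.9 ± 12.5 and 42.8 ± 1.7 normalised counts (adjusted p 0.406, and 0.0488 without control replicate 2).

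Among genes outside the lists, Rin2, Cd28 and Etv5 were also among the 5 deepest falls, with log2 fold changes of -2.51, -2.01 and -1.95. Etv5, a transcription factor downstream of ERK signalling, went from 186 ± 17.9 to 47.8 ± 8.18 normalised counts. Of 15 histone lysine demethylase genes, Kdm4a rose from 49.8 ± 13.1 to 224 ± 17.6 normalised counts, as measured on 1 of its 2 records. Kdm6b, which acts on histone H3 lysine 27, rose from 12.8 ± 3.78 to 35.4 ± 9.47 (log2 fold change 1.51, adjusted p 0.0476). The same 2 genes passed when adjusted over the list alone. The list had a camera adjusted p of 0.248, whereas fry called it higher with an adjusted p of 0.00652. For Kdm6b the adjusted p was 0.511 without LPS replicate 2 and 0.0551 without control replicate 2, 0.0546 with DESeq2 size factors, 0.0514 without the 5 most abundant records, 0.0649 with limma-voom and 0.276 in the DESeq2 Wald test, and it ran from 0.000721 to 0.511 over the alternatives. Of 7 measured immune long non-coding RNAs, Ptgs2os2, which lies 50.8 kb from Ptgs2, rose from 1.97 ± 0.796 to 12.4 ± 0.491 normalised counts (adjusted p 0.0417), Mir22hg was higher and Dnmt3aos lower when adjusted over the list alone, and the list had a camera adjusted p of 0.685. Leaving out control replicate 2, LPS replicate 1 or LPS replicate 2 gave Ptgs2os2 an adjusted p of 0.0603, 0.357 and 0.406, the robust dispersion 0.0519 and the DESeq2 Wald test 0.388.

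None of 20 S phase and DNA replication genes passed in edgeR, DESeq2 or limma-voom or when adjusted over the list alone, and 4 had an unadjusted p below 0.05. All 20 had a negative sign in edgeR, and the median was -0.30 with a camera adjusted p of 0.00813. The adjusted p of that list was 0.372 with an estimated correlation, and its most abundant member, Rrm1, had 1115 ± 13.2 and 1011 ± 50.6 normalised counts. None of 17 G2 and M phase genes passed in any of the 3 tools or when adjusted over the list alone, and 0 had an unadjusted p below 0.05 (camera adjusted p 0.611), with Ccna2 at 722 ± 54.3 and 684 ± 17.9. Histone genes, which are mostly not polyadenylated, were listed in advance as a sign of RNA quality, and their copies can share reads. Among genes taken by their symbol pattern, 3 of 51 measured fell (H2bc14, H3c2 and H2bc21, log2 fold changes -0.78, -0.90 and -1.15), and 10 when adjusted over the list alone. With H13 and H1f0 left out, 8 of 49 were lower when adjusted over the list alone. The histone list median was -0.47 with a camera adjusted p of 6.51e-09, and the adjusted p was 0.534 with an estimated correlation and 0.281 by fry. None of the 3 was called without LPS replicate 1 or without LPS replicate 2, with adjusted p from 0.134 for H3c2 without LPS replicate 1 to 0.804 for H3c2 without LPS replicate 2, and the DESeq2 Wald test gave H2bc21 0.201. None of 80 genes taken by the symbol pattern for ribosomal proteins passed in the 3 tools or when adjusted over the list alone, and 1 had an unadjusted p below 0.05, the S6 kinase gene Rps6ka4 (median 0.08, camera adjusted p 0.361). With 7 S6 kinase genes and Rps19bp1 left out, none of 72 genes passed in edgeR or when adjusted over the list alone and 0 had an unadjusted p below 0.05 (median 0.08, camera adjusted p 0.433), and Rplp0 had 7770 ± 1639 and 8233 ± 96.5 normalised counts. Without control replicate 1 the ribosomal protein list was called higher with an adjusted p of 0.00639, and Rplp0 had an adjusted p of 0.0150. None of 56 small structured RNAs passed either, and 2 had an unadjusted p below 0.05 (median -0.13, camera adjusted p 0.142, and 0.0411 without LPS replicate 1).

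Of the sentinel genes, 7 fell below the count filter. Tnf had 1 and 2 counts in the controls and 7 and 9 after LPS over its 2 records, and Ccl5 had 0 in the controls and 3 and 4 after LPS. Tnfaip3 had 1 count in the controls and 17 after LPS over 2 records, and Irf7 had 0 counts in every library over its 3 records. P2ry12 had 3 and 5 counts in controls and 1 and 0 after LPS, Cx3cr1 had 4 and 2 and then 9 and 8, and Trem2 had 1 count in all. Without a filter on low counts none of their records passed, and the lowest adjusted p were 0.106 for 1 record of Tnfaip3 and 0.130 for Tnf. Osm, Dusp6, Tlr13, Ticam1, Fdft1, Rps6ka4 and the genes given as passing only over a list alone, apart from Arg1, fell outside the naming rule and were chosen after their values were seen.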

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

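The tests with robust dispersion, without the 5 most abundant records, with counts summed per gene, with limma-voom, with genes of another kind left out of the pattern lists and with the GC and length trend removed were chosen only after the result was seen. Over all alternatives run, none of the 386 called genes changed direction where tested and no called list did in its test, whereas the median of the Toll-like receptor list went from 0.01 to -0.10 with a mean of at least 50 normalised counts and to -0.14 without LPS replicate 2. The groups of all 386 genes did not overlap, so refitting the same counts could hardly reverse a sign, and the unchanged directions are no separate evidence. Leaving genes of another kind out of the pattern lists gave 10 lists higher and 3 lower, with an adjusted p of 5.75e-09 for histone genes. Of 59 named calls, 40 held in every setting in which the gene was tested, and some low-count genes among them were not tested in all settings. All 386 called genes were also called without a filter and with the GC trend removed, 370 with DESeq2 size factors, 361 with limma-voom and 267 with the DESeq2 Wald test. With a mean of at least 50 normalised counts, where fewer records are tested, 164 genes were higher and 54 lower, 145 and 42 of them at least 2-fold. No filter gave 209 lower, 172 at least 2-fold. The Wald test gave 66 lower, 57 at least 2-fold, and the GC trend removed gave 435 higher and 337 lower. Leaving out 1 library gave 165 (without LPS replicate 2) to 723 higher (without control replicate 2) and 39 to 581 lower, and at least 2-fold 165 to 391 higher and 39 to 217 lower, with the same libraries at each end. The lone sample of a group is then assumed to vary like the other group, so the spread comes from the remaining pair alone. Without an LPS library that is the control pair, which differed more than the LPS pair. With an estimated correlation camera called 0 lists higher and 0 lower, against 10 and 3. The NF-kB list lost its call although its estimated correlation, 0.00976, was near the preset 0.01. A higher correlation therefore does not account for that loss, nor for that of the Toll-like receptor list, estimated at -0.0768. With an estimated correlation, camera takes its degrees of freedom from the 4 libraries rather than from the number of genes. These lost calls therefore do not decide whether a list changed. Fry called 12 higher and 1 lower, and 2 of the 12 were not called by camera: histone lysine demethylases (adjusted p 0.00652) and the unfolded protein list (0.0129). Except for the number of records, the cause was not tested. Alternatives planned for normalised values only were not run, since the values are counts. On counts simulated at this depth and sample number, the fit recovered 51 of 100 2-fold changes, and 84.1% of those with a mean count of at least 100. Depth was not varied apart from sample number.

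A replicate block, which pairs same-numbered samples, gave 401 higher and 288 lower, 169 of the latter at least 2-fold. The block also called Tlr4 (log2 fold change -0.82, adjusted p 0.0226) and Arg1 (-1.56, 0.00197) lower. The labels do not state a pairing, and the correlation of deviations between same-numbered samples was 0.231, so the cause was not tested.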

Other observations

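The tests of neighbouring genes, of uncounted shared reads, of ubiquitous genes with other kinds left out, of the highest share of LPS RNA, of records that differ little between the groups and of draws matched on AT content were chosen only after the result was seen. Genes that rose lay next to each other in several places. Among 236 genes at least 2-fold higher, 28 adjacent pairs lay within 100 kb, of which 4 overlapped, against a mean of 9.52 and a highest value of 24 in 10000 random draws of tested genes (permutation p 0.0001, the smallest these draws can give). The pairs included the monocyte chemokine genes Ccl2 and Ccl7, 8.26 kb apart, the interleukin-1 genes Il1a and Il1b, 54.4 kb apart, and the antiviral genes Rsad2 and Cmpk2, 12.7 kb apart, and Oas2 and Oas3, 3.21 kb apart. Among 107 genes at least 2-fold lower there was 1 pair, against a mean of 2.00 (permutation p 0.866). These pairs were chosen after their values were seen.

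Genes with several RefSeq records had low counts: 6.27% of 4765 such genes reached a mean count of 10, against 34.4% of 19014 genes with 1 record. Low expression is argued against by ubiquitous genes, of which 3 of 26 with several records and 107 of 124 with 1 record reached it, 74.8 percentage points fewer, and 83.3 with S6 kinase genes, Rps19bp1 and pseudogenes left out. Within genes, the count of a record rose with the percent of its exonic bases that no other record holds (Spearman's rho 0.514 across 3729 records, which are not independent). A candidate explanation is that reads shared between overlapping records were left uncounted, so low counts of Tnf, Trem2, Tnfaip3 and Irf7, and of Gapdh with 3, 8, 10 and 9 counts, may not measure their expression. The groups of the design give no other biological explanation to test.

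The control libraries differed from each other more than the LPS libraries, with a ratio of the SDs of the log2 ratio of 2.13 over 4112 records. Depth is argued against by a ratio of 1.87 (95% interval 1.804 to 1.933) after thinning every library to 902176 counts, and a GC or length trend as the whole cause by 1.49 (1.42 to 1.55) after its removal, although the trend held 58.7% of the variance of the control ratio and 14.8% of the LPS ratio. LPS RNA in a control library is argued against by an SD of 0.161 (upper limit 0.232) from the highest share its most induced transcripts allow, where 0.443 was needed, and by a ratio of 2.12 among 3434 records that differ little between the groups. The median control ratio of 32 records at least 16-fold higher was -0.0166 on the log2 scale (interval -0.748 to 0.158), too wide to decide alone. All these intervals are over records, which are not independent, of a single library pair per group. They do not show how such a ratio would vary between library pairs. A GC trend may therefore be part of the difference, the rest stays open, and no biological explanation was tested.

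Of 229 genes at least 2-fold higher with an annotated 3' UTR, 44.5% held the AU-rich heptamer TATTTAT, a motif of mRNA decay, against 29.8% of genes matched on UTR length and mean count, a ratio of 1.49, while 27.4% of 106 genes at least 2-fold lower held it against 38.0% of matched genes (95% of draws from 30.2% to 46.2%). Long or AT-rich UTRs are argued against by a ratio of 1.55 after matching on AT content too, where the highest of 1000 draws held 38.0% against 44.5%. Other heptamers of the same composition had a median ratio of 1.06, but TTATTTA, which overlaps it, reached 1.58. Whether this heptamer or a related AU-rich element goes with the rise cannot be told apart, since the 2 motifs overlap in sequence. LPS treatment stays open as the biological explanation, and it was not tested apart from the motif.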
